A study of Mus musculus with 2 samples.

How the data were processed

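The samples were thalamic tissue of 2 wildtype C57BL/6J mice at 2 months of age, 1 library each. Per the labels, tissue was digested with papain, protease and dispase in choline chloride solution, and libraries were made with the 10x 3' v3 kit and sequenced on an Illumina NovaSeq. Per the submitters' processing notes, Cell Ranger 7.1.0 and the mm10 genome were used, and Seurat 5 is named with no role. The deposited values are counts, that is raw UMI counts per gene and barcode for barcodes that the authors' pipeline kept, and every barcode held at least 500 UMIs. The annotation version and the use of intron reads and strand in the counting are not given in the sources used here. Of 32285 genes, 32158 had an identifier in GENCODE vM21, from which coordinates (GRCm38) were taken. Read quality and mapping rates were not analysed here.

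Cells were kept with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs. In mouse 1, 1156 of 7889 barcodes were below the minimum and 503 above the mitochondrial limit, and in mouse 2 these were 1849 and 1021 of 12107. Scrublet, run per mouse with an expected rate of 0.8% per 1000 barcodes, removed 181 and 262 doublets (2.84% and 2.78% of the passing barcodes, where 6.31% and 9.69% were expected). Kept cells had a median of 17998 UMIs in mouse 1 and 14759 in mouse 2. Counts were scaled to 10000 per cell and log-transformed. With mouse as batch, 2000 variable genes were chosen, followed by 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, scipy 1.17.1, numpy 2.4.6). No integration across mice was applied. Mitochondrial, ribosomal protein and haemoglobin genes and all genes of the read-out lists were held out of the variable genes. Clusters were named from marker lists, with at least 3 markers required, and every class is called "-like" because no outside reference was used. Pericyte-like and smooth muscle-like cells were summed as mural-like. Clusters that mixed markers of unrelated classes, or whose leading genes held more markers of another class, stayed unnamed and out of the tests. Ependymal-like cells were named but, with 4 cells in mouse 1, were too few to test.

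The comparisons, gene lists, rules and first set of alternatives were chosen before the data were examined. Counts were summed per mouse and class, giving 26 sums for 13 classes with at least 20 cells in each mouse. Sums were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1): TMM scaling, filterByExpr, and a robust quasi-likelihood fit on class plus mouse. The mouse entered as a block because every class comes from the same 2 animals. The fit covered 17605 genes with 12 residual degrees of freedom, a common biological coefficient of variation of 0.236 and a median prior of 6.94 degrees of freedom. The spread is shared over classes and rests on 2 animals. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 fold change of at least 1. Adjustment was over all tested genes, and for each list also over the list alone. The comparisons were glutamatergic against GABAergic, habenular against glutamatergic, neuronal against non-neuronal, astrocyte-like against the other classes, microglia-like against the other classes, microglia-like against border macrophage-like, oligodendrocyte-like against precursor-like, and endothelial-like against mural-like. The same counts served clustering and testing, so p-values are too small to some degree, and genes that define clusters are not reported as results.

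Lists covered ionotropic and metabotropic glutamate receptors, GABA receptors, calcium and HCN channels, potassium channels, neuromodulator receptors, neuropeptides, thalamic nucleus-related genes, transmitter uptake and glutamine cycle, glycolysis and lactate transport, cholesterol synthesis, phosphate handling and calcification, Alzheimer disease risk gene orthologs, immediate early and stress genes, lysosome and phagocytosis, cytokines with chemokines and complement, antigen presentation, cell cycle, blood-brain barrier, vascular signalling and basement membrane. From each list read out in a comparison, up to 4 called genes with the largest absolute log2 fold change were named, given the same direction in each mouse and at least 50 CPM on the higher side. Up to 3 genes higher and 3 lower were added from outside the lists, the marker lists and the variable genes. Predicted gene models and mitochondrial or ribosomal protein genes were left out. Of the resulting 200 pairs of gene and comparison, those with 3 or fewer UMIs on one side are not printed, a choice made after their values were seen, and a few other pairs are not reported here. Members of a list named to describe a count of 3 or fewer were also chosen after their values were seen. Every measured phosphate list gene is given with its class of highest CPM, and 1 listed symbol was not matched. Thalamic nucleus-related genes were named by cluster where the highest cluster was at least 4-fold above the median cluster and at least 50 CPM in each mouse.

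Shares of cells have exact 95% binomial intervals, which cover counting error only. Mouse 2 was set against mouse 1 within classes with no test, as log2 ratios of CPM + 1 for list genes at 5 CPM or more, and each list median was placed among 10000 random lists matched on expression. The fit was tested on simulated data with 200 changed genes per comparison. In the order above, of 17468, 17465, 17064, 17370, 17455, 17440, 17507 and 17423 genes, the share of 4-fold changes recovered was 89%, 92%, 100%, 99%, 96%, 90%, 95% and 89%. For 2-fold changes it was 27%, 33%, 98%, 67%, 69%, 13%, 27% and 26%. Of the genes found significant, 5.69%, 6.02%, 6.60%, 8.29%, 4.07%, 6.36%, 6.87% and 1.71% were false. The simulated counts used the fit's own estimate of spread, and as many genes were raised as lowered, none of them at low expression. The real comparisons called far more genes, and clustering was not repeated. These shares therefore do not cover the use of the same counts for clustering and testing.

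Alternatives were DESeq2 size factors in the same fit, DESeq2 1.42.0 as the test, no gene filter, no mouse block, resolution 0.5 and 2, a mitochondrial limit of 5%, a looser cell filter (200 genes, no UMI minimum), doublets kept, list genes allowed in clustering, count splitting with probability 0.5, and each mouse left out in turn. With 1 mouse no residual degrees of freedom remain, so log2 CPM differences (prior count 2) were used. Counts given for 1 mouse alone are of genes called with both mice that kept direction and size there. Size was kept at an absolute log2 difference of at least 1, so such counts cannot exceed the reported ones. Added after seeing the data were fits without the neuron-like clusters of low UMI counts (13, 17, 22, 23 and 27) and without microglia-like cluster 11.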

Results

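Thalamic tissue from 2 wildtype C57BL/6J mice, a common inbred laboratory strain, was dissociated at the age of 2 months and profiled by droplet-based single-cell RNA sequencing, with 1 library per mouse. The thalamus relays sensory and motor signals to the cortex, and the habenula lies next to it. Both mice were untreated and form a single group, and the title of the series gives the thalamic expression profile at this age as its subject. The comparisons therefore set cell classes from the same 2 animals against each other. The library of mouse 1 held 163418203 unique molecular identifiers (UMIs) in 7889 barcodes, with a median of 15067 UMIs and 4280 genes per barcode. That of mouse 2 held 204839993 UMIs in 12107 barcodes, with medians of 11837 UMIs and 3837 genes. After filtering, 6185 cells of mouse 1 and 9176 of mouse 2 formed 38 clusters. Throughout, CPM, the counts of a gene scaled to the depth of its class, are given as mean ± SD with n = 2 mice, and log2 fold changes as estimate ± SE.

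Oligodendrocyte-like cells, which make myelin, were the largest class in both mice, with 31.8% of kept cells in mouse 1 (95% exact binomial interval 30.7 to 33.0) and 35.9% in mouse 2 (34.9 to 36.9), a mean of 33.9% ± 2.90 (SD, n = 2). Astrocyte-like cells made up 16.7% (15.8 to 17.7) and 3.96% (3.57 to 4.38), microglia-like cells 14.5% (13.6 to 15.4) and 5.68% (5.21 to 6.17), and endothelial-like cells 10.2% (9.46 to 11) and 5.82% (5.35 to 6.32). All neuron-like classes together held 8.49% (7.81 to 9.21) in mouse 1 and 27.3% (26.4 to 28.2) in mouse 2. Among these were glutamatergic neuron-like cells at 3.30% (2.87 to 3.77) and 17.4% (16.7 to 18.2), habenular neuron-like cells at 2.31% (1.95 to 2.72) and 3.81% (3.43 to 4.23), and GABAergic neuron-like cells at 0.776% (0.573 to 1.03) and 0.687% (0.528 to 0.878). Neuron-like cells given no subclass by the marker rules, called unresolved, made up 2.10% (1.76 to 2.49) and 5.37% (4.92 to 5.85). Among their clusters, only cluster 23 was marked as mixing glutamatergic and GABAergic markers. Oligodendrocyte precursor-like cells stood at 2.30% (1.94 to 2.70) and 10.5% (9.85 to 11.1). Smaller classes had mean shares of 3.92% ± 1.57 for pericyte-like, 1.73% ± 0.933 for smooth muscle-like, 1.20% ± 0.599 for committed oligodendrocyte precursor-like, 1.19% ± 0.907 for border macrophage-like, 0.431% ± 0.130 for vascular leptomeningeal fibroblast-like and 0.190% ± 0.178 for ependymal-like cells. Unnamed clusters held 6.92% of cells in mouse 1 and 2.64% in mouse 2. Intervals cover counting error only. With 1 mouse on each side no test was possible, and dissociation with papain, protease and dispase can set these shares.

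**Figure D1:**
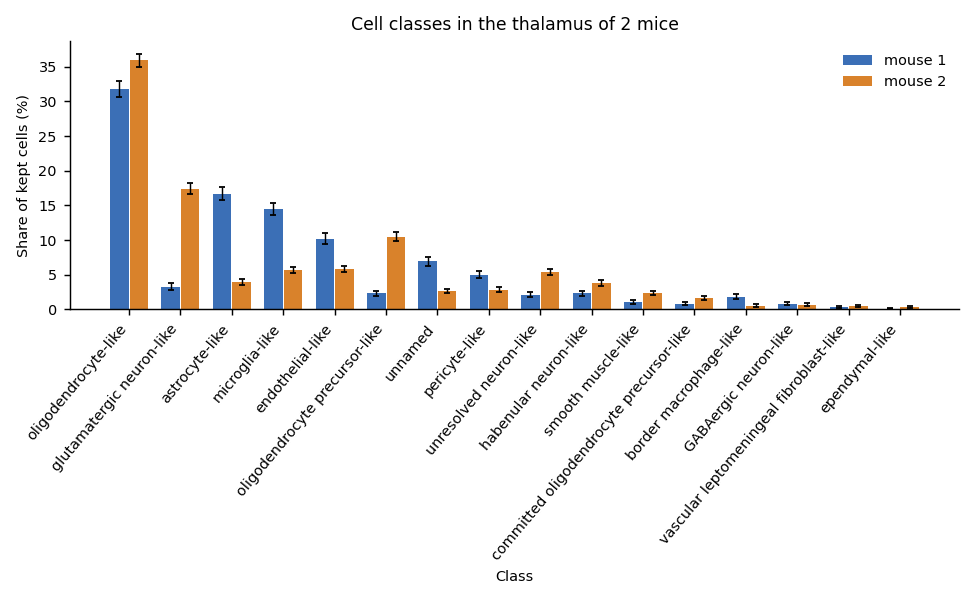
Share of kept cells (%, vertical axis) in each named class and in the unnamed clusters (horizontal axis) for mouse 1 (blue) and mouse 2 (orange), with 95% exact binomial intervals that cover counting error only. Oligodendrocyte-like cells lead in both mice at 31.8% and 35.9%, while glutamatergic neuron-like cells hold 3.30% and 17.4%.

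Glutamatergic neuron-like cells differed from GABAergic neuron-like cells in receptors, channels and peptides. Gabra4 and Gabrd, subunits of extrasynaptic GABA-A receptors, were higher in glutamatergic cells by log2 fold changes of 4.83 ± 0.57 (621 ± 157 against 30.8 ± 13.7 CPM) and 4.39 ± 0.51 (121 ± 51.1 against 7.44 ± 2.09 CPM). Cacna2d1, an auxiliary calcium channel subunit, was higher by 5.52 ± 0.64 (518 ± 110.1 against 18.6 ± 17.3 CPM), and Cck, which encodes the peptide cholecystokinin, by 5.46 ± 0.44 (653 ± 86.7 against 19.1 ± 10.8 CPM). GABAergic cells had more Sst, the precursor of somatostatin, with a log2 fold change of −10.49 ± 1.36 (0.377 ± 0.143 against 479 ± 229 CPM), and more Pnoc, the precursor of nociceptin (−3.17 ± 0.56). In the edgeR quasi-likelihood (QL) test with Benjamini-Hochberg (BH) adjustment, Gabra4 (ENSMUSG00000029211, chromosome 5, 71569749 to 71658308, GRCm38) had an adjusted p of 1.09e-05, Cck 1.99e-07 and Sst 3.37e-05. Of 17605 genes tested, 2131 were called, 1312 higher and 819 lower in glutamatergic cells, and 2112 of them had the same direction in each mouse. With DESeq2 size factors, which shifted the median of all genes by −0.15 on the log2 scale, the split was 1016 higher and 974 lower.

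Among ionotropic glutamate receptors, 7 of 18 were higher and none lower (8 and 0 adjusted over the list alone). Grin2c, an NMDA receptor subunit, was higher by 2.41 ± 0.38, Grin2a by 2.22 ± 0.52 (a call lost without the mouse block) and Grin2b by 2.23 ± 0.68. Only 1 to 4 members were called higher under 8 of the alternatives, and 4 of the 7 kept direction and size in mouse 2 alone. The calls of Grin2b and of Gria3 (1.25 ± 0.40) were each lost under 8 or more alternatives, and Gria3 stood at 1.66 in mouse 1 and 0.62 in mouse 2. Metabotropic glutamate receptors had 3 higher and 1 lower of 7 tested (4 and 1 adjusted over the list alone), with Grm4 at 3.61 ± 0.46 and Grm3 lower at −2.95 ± 0.46. GABA receptors had 5 higher and none lower of 14 (5 and 0 adjusted over the list alone, and 3 higher without the mouse block or at a mitochondrial limit of 5%). Gabbr2, a GABA-B receptor subunit, rose by 2.58 ± 0.48, and Gabrb2 stood at 2.53 in mouse 1 and 1.12 in mouse 2 with its call lost under 7 alternatives. Calcium and HCN channels had 7 higher and 3 lower of 19 (9 and 4 adjusted over the list alone). Cacna1g, a T-type channel of burst firing, was higher by 2.60 ± 0.37, Cacna1c by 2.73 ± 0.48, and Cacna2d2 lower at −1.91 ± 0.32. Potassium channels had 11 higher and 4 lower of 32 (12 and 4 adjusted over the list alone). Kcnn3 was higher by 3.34 ± 0.49, Kcnip4, a Kv4 channel-interacting protein, by 3.73 ± 0.65 and Kcnc2 by 3.45 ± 0.57, the last 2 not called without the mouse block, where 5 members were higher and 2 lower, and 2 were also lower in mouse 2 alone. Kcnc4, a fast-spiking Kv3 channel, was lower at −2.51 ± 0.51.

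Neuromodulator receptors had 8 higher and 15 lower of 44 (11 and 17 adjusted over the list alone). The adenosine receptor Adora1 (2.87 ± 0.42) and the adrenergic receptors Adra1b (2.75 ± 0.47) and Adrb1 (2.60 ± 0.57) were higher. The cannabinoid receptor Cnr1 was lower at −2.32 ± 0.55, with −3.74 in mouse 1, −1.46 in mouse 2 and no call without the mouse block. Neuropeptides had 3 higher and 11 lower of 21 (4 and 12 adjusted over the list alone), and Npy was lower at −3.54 ± 0.71 (5.06 ± 3.75 against 76.3 ± 78.5 CPM). Outside the lists, the transcription factor Lhx9 (6.82 ± 0.62), Cnksr3 (6.77 ± 0.50) and the zinc transporter Tmem163 (6.20 ± 0.55) were higher. The transcription factors Gata3 (−9.11 ± 0.71) and Lhx1 (−8.73 ± 1.04) and the complexin Cplx3 (−7.39 ± 0.99) were lower. RNA quality differed between these classes: messenger RNA of cytosolic ribosomal proteins made up 1.53% of UMIs in mouse 1 and 2.46% in mouse 2 in glutamatergic cells, against 3.93% and 3.82% in GABAergic cells. Glutamatergic clusters 13 and 17, of low UMI counts, held 61 and 7 of 204 glutamatergic cells in mouse 1 and 417 and 314 of 1600 in mouse 2. GABAergic cells of mouse 1 had a mean of 444 haemoglobin UMIs per cell, with a median of 7.5. Without all neuron-like clusters of low UMI counts, an alternative chosen after seeing the data, 1725 genes were called, 987 higher and 738 lower, with 2 ionotropic receptors, 3 GABA receptors, 4 calcium or HCN channels and 7 potassium channels higher.

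Habenular neuron-like cells carried some nicotinic and serotonin receptors that were scarce in glutamatergic neuron-like cells. Chrnb4 and Chrnb3, subunits of nicotinic acetylcholine receptors, were higher by 8.81 ± 0.69 (158 ± 4.18 against 0.285 ± 0.0266 CPM) and 8.35 ± 0.58 (131 ± 68.3 against 0.310 ± 0.0876 CPM), and the serotonin receptors Htr5b and Htr4 by 7.90 ± 0.72 and 7.33 ± 0.58. Cacna1a, the P/Q-type calcium channel, was lower at −6.15 ± 0.40 (9.23 ± 6.40 against 552 ± 98.1 CPM), as was Kcnc1, a Kv3 potassium channel, at −6.53 ± 0.51 (2.94 ± 0.738 against 235 ± 124 CPM). Ramp3, a receptor activity-modifying protein, was lower at −7.12 ± 0.60 (1.74 ± 0.585 against 216 ± 77.7 CPM) and the homeobox gene Gbx2 at −6.89 ± 0.68. Chrnb4 (ENSMUSG00000035200, chromosome 9, 55028154 to 55048779) had an edgeR QL adjusted p of 3.41e-08, Cacna1a 3.17e-09 and Ramp3 4.39e-08. In all, 3673 genes were called, 1529 higher and 2144 lower in habenular cells, with 3665 in the same direction in each mouse.

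In this comparison 13 of 44 neuromodulator receptors were higher and 18 lower (13 and 19 adjusted over the list alone). Calcium and HCN channels had 2 higher and 10 lower of 19 (3 and 10 adjusted over the list alone), with Cacna1b at −6.09 ± 0.65, Cacna2d1 at −6.00 ± 0.64 and Cacng2 at −4.83 ± 0.67. Potassium channels had 2 higher and 15 lower of 32 (3 and 15 adjusted over the list alone), among them Kcnc2 at −6.71 ± 0.67, Kcnip4 at −5.83 ± 0.72 and the M-current channel Kcnq3 at −5.61 ± 0.59. Neuropeptides and granins had 4 higher and 9 lower of 21 (4 and 10 adjusted over the list alone): Scg3 was higher by 2.37 ± 0.28, and Vgf (−4.51 ± 0.40), Cck (−3.58 ± 0.39) and Chga (−1.54 ± 0.28) were lower. Thalamic nucleus-related genes had 5 higher and 10 lower of 24 (6 and 11 adjusted over the list alone), including Tnnt1 at −6.92 ± 0.65 and Necab1 at −6.61 ± 0.52. Outside the lists, Syt15 (8.27 ± 0.95), the homeobox gene Irx5 (7.86 ± 0.45) and Wfikkn2 (7.57 ± 0.68) were higher, and Syndig1, which acts in synapse development, (−7.85 ± 0.64) and Slitrk6 (−7.09 ± 0.72) were lower. Ribosomal protein messenger RNA made up 2.82% and 3.62% of UMIs in habenular cells of mouse 1 and mouse 2, against 1.53% and 2.46% in glutamatergic cells. Without the neuron-like clusters of low UMI counts, 90 and 226 habenular cells remained and 3518 genes were called, 1451 higher and 2067 lower.

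Thalamic nucleus-related genes differed between clusters of neuron-like cells, and some peaked in a single one. The calcium-binding protein Necab1 peaked in glutamatergic cluster 10 at 944 ± 2.59 CPM, with Gbx2 at 128 ± 6.21 CPM. Calb2, another calcium-binding protein, was shared by cluster 10 (975 ± 73.2 CPM) and unresolved cluster 20 (923 ± 108 CPM), and the higher of them differed between the mice. Rorb, a nuclear receptor, was likewise shared by glutamatergic clusters 10 (470.2 ± 11.6 CPM), 13 (414 ± 100 CPM) and 15 (409 ± 12.9 CPM). Tnnt1, a troponin of the core relay nuclei, and Ramp3 peaked in glutamatergic cluster 15 at 283 ± 88.6 and 359 ± 14.6 CPM. The zinc finger genes Zic1 and Zic4 peaked in habenular cluster 18 at 1023 ± 104 and 274 ± 43.5 CPM. Cerebellin genes, whose products organise synapses, peaked in unresolved cluster 25, with Cbln1 at 519 ± 106, Cbln2 at 359 ± 14.5 and Cbln4 at 592 ± 78.6 CPM. Rora, which was also high in cluster 15 (3063 ± 398 CPM), and Grid2ip peaked in glutamatergic cluster 13 (3779 ± 122 and 107 ± 33.7 CPM) and Nfib in habenular cluster 22 (453 ± 82.2 CPM), both clusters of low UMI counts. Each of these genes was at least 4-fold above the median cluster, and above 50 CPM, in each mouse in its cluster of highest mean. Only clusters with at least 20 cells in each mouse were compared. This left out glutamatergic cluster 17 (7 and 314 cells in mouse 1 and mouse 2), which had Necab1 among its leading genes, and unresolved cluster 27 (9 and 103). Cluster 10 had only 23 cells in mouse 1. No test was run on clusters.

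**Figure D2:**
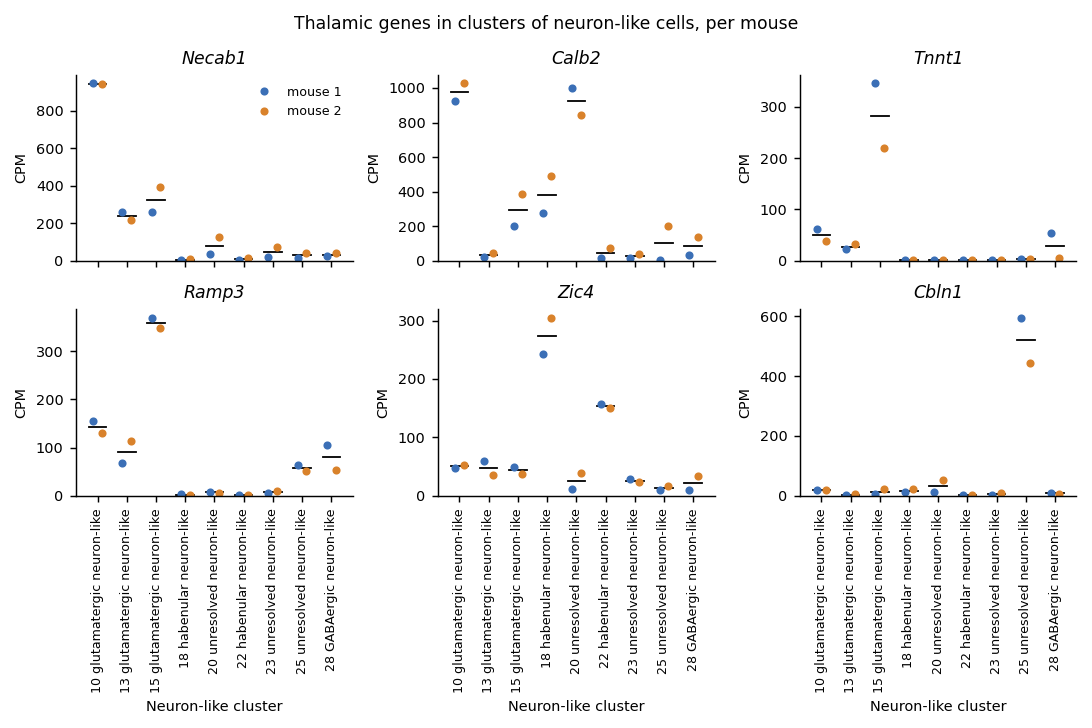
CPM (vertical axes) of 6 thalamic nucleus-related genes in the clusters of neuron-like cells with at least 20 cells in each mouse (horizontal axis, cluster number and class), with points for mouse 1 (blue) and mouse 2 (orange) and a bar at their mean. Necab1 peaks in cluster 10, Calb2 in clusters 10 and 20, Tnnt1 and Ramp3 in cluster 15, Zic4 in cluster 18 and Cbln1 in cluster 25.

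Neuron-like classes were set against the non-neuronal classes to compare energy, lipid, phosphate and disease-related genes. Eno2, the neuronal enolase, was higher in neurons by a log2 fold change of 4.10 ± 0.17 (255 ± 54.0 against 14.9 ± 5.13 CPM), as was the neuronal glucose transporter Slc2a3 by 2.75 ± 0.15 (70.5 ± 8.80 against 15.1 ± 3.49 CPM). Apoe, the main lipid carrier of the brain, was lower at −4.72 ± 0.29 (51.1 ± 38.1 against 4224 ± 303 CPM), and the lipid exporter Abca1 at −3.93 ± 0.13 (9.28 ± 0.502 against 202 ± 8.87 CPM). The hexokinase Hk2 was lower at −4.07 ± 0.37 (0.731 ± 0.155 against 53.5 ± 4.36 CPM). Here fold changes compare means of log-scale coefficients over classes, so they can differ from the ratio of the mean CPM, to which the richest class adds most. Eno2 (ENSMUSG00000004267, chromosome 6, 124760053 to 124769673) had an edgeR QL adjusted p of 9.33e-14 and Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188) of 1.96e-11. Of the 17605 genes, 6757 were called, 4183 higher and 2574 lower in neurons, and 6739 had the same direction in each mouse.

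Glycolysis and lactate transport genes had 12 higher and 5 lower of 23 in neurons (12 and 5 adjusted over the list alone, with 3 lower in mouse 1 alone and under 2 alternatives), and Ldhb was higher by 2.39 ± 0.12. Cholesterol synthesis genes had 2 higher and 2 lower of 24 (2 and 2 adjusted over the list alone), and the lower count was 0 or 1 under most alternatives. Of these calls, no lower one kept its direction and size in mouse 2 alone, and no higher one in mouse 1 alone. Fdft1, squalene synthase, stood at 1.06 ± 0.18 with 0.70 in mouse 1 and 1.93 in mouse 2, and lost its call at a mitochondrial limit of 5% and with doublets kept. Phosphate handling and calcification genes had 2 higher and 6 lower of 15 (2 and 6 adjusted over the list alone, with 1 higher in mouse 2 alone). Enpp1, which makes pyrophosphate, was lower at −2.50 ± 0.33, Pdgfrb at −1.97 ± 0.30 and Jam2 at −1.90 ± 0.19, while the phosphatase Alpl at −2.45 ± 0.82 lost its call without the gene filter and with the looser cell filter. Alzheimer disease risk gene orthologs had 2 higher, Sorl1 and Mapt, and 14 lower of 28 (2 and 14 adjusted over the list alone, with none higher when doublets were kept). Both calls are against the mean of the non-neuronal classes: in each mouse Sorl1 was highest in astrocyte-like and Mapt in oligodendrocyte-like cells. The phosphatase Inpp5d was lower at −2.62 ± 0.42 and progranulin, Grn, at −2.18 ± 0.12. Immediate early and stress genes had 4 higher and 23 lower of 32 (4 and 23 adjusted over the list alone). Socs3 was lower at −4.48 ± 0.52, Zfp36 at −4.37 ± 0.44, Nfkbia at −3.13 ± 0.34 and Atf3 at −3.68 ± 0.36, the last with −2.39 in mouse 1 and −3.83 in mouse 2. Outside the lists, the sodium channel Scn9a (7.56 ± 0.23) and the ubiquitin ligase March4 (6.93 ± 0.23) were higher. Nrg3os, an antisense transcript at Nrg3, stood at 7.79 ± 0.23, a value that is uncertain because the strand setting of the counting is not given in the sources used here. Tmem100 (−5.48 ± 0.55), Arhgap31 (−5.16 ± 0.19) and the phospholipase Pld1 (−4.90 ± 0.19) were lower.

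Astrocyte-like cells differed from the other classes in genes of transmitter uptake, in potassium channels and in receptors. Slc6a11, the GABA transporter GAT3, was higher than the mean of the other classes by 8.18 ± 0.27 (2126 ± 60.2 against 11.2 ± 4.41 CPM), and Slc1a2, the glutamate transporter GLT-1, by 6.41 ± 0.16 (3918 ± 144 against 139.9 ± 0.818 CPM). The inward rectifiers Kcnj16 and Kcnj10 were higher by 6.66 ± 0.39 and 4.81 ± 0.20 (561 ± 42.9 against 59.4 ± 3.52 CPM), and the histamine receptor Hrh1 by 6.80 ± 0.30 (121 ± 18.8 CPM). Myorg, a glycosidase tied to brain calcification, was higher by 6.65 ± 0.21 (99.5 ± 5.64 against 1.37 ± 0.364 CPM). Slc6a11 (ENSMUSG00000030307, chromosome 6, 114131241 to 114249952) had an edgeR QL adjusted p of 4.76e-15, Kcnj10 1.01e-13, and Myorg 2.96e-15. Calls numbered 5811, 3683 higher and 2128 lower, with 5769 in the same direction in each mouse, and leaving out the gene filter moved the median of all genes by −0.10. Ribosomal protein messenger RNA made up 0.465% and 0.565% of UMIs in astrocyte-like cluster 14 (389 and 47 cells in mouse 1 and mouse 2), against 1.23% and 0.925% in cluster 6 (644 and 316 cells).

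Among glutamate and GABA uptake and glutamine cycle genes, 10 of 19 were higher in astrocyte-like cells and 3 lower (10 and 3 adjusted over the list alone), with 5 lower by DESeq2 and 6 at a mitochondrial limit of 5%. The mitochondrial glutamate carrier Slc25a18 was higher by 7.29 ± 0.18 and the glutamine transporter Slc38a3 by 5.58 ± 0.25. Cholesterol synthesis genes had 15 higher and none lower of 24 (15 and 0 adjusted over the list alone), with Msmo1 at 3.04 ± 0.17, Nsdhl at 2.71 ± 0.19 and Fdft1 at 2.17 ± 0.24. Glycolysis and lactate transport genes had 9 higher and 4 lower of 23 (9 and 4 adjusted over the list alone). Pfkm (3.10 ± 0.15), Pfkfb3 (2.84 ± 0.18) and Pfkp (2.79 ± 0.29), which act at the phosphofructokinase step, were higher, and the lactate transporter Slc16a7 was lower at −3.72 ± 0.42. Neuromodulator receptors had 9 higher and 5 lower of 44 (9 and 4 adjusted over the list alone), a lower count that was 13 by DESeq2, 8 with doublets kept and 3 with count splitting. The adrenergic receptors Adra2a (5.92 ± 0.34) and Adra1a (5.40 ± 0.33) were higher and the muscarinic receptor Chrm3 was lower at −2.82 ± 0.60. Potassium channels had 13 higher and 9 lower of 32 (13 and 9 adjusted over the list alone), with Kcnn2 at 5.42 ± 0.14 and Kcnk1 at 4.73 ± 0.19. Outside the lists, Cyp4f15 (9.86 ± 0.37), Ccdc190 (9.48 ± 0.28) and the tubulin ligase Ttll8 (9.17 ± 0.30) were higher. The phosphatase Ptpre (−4.22 ± 0.42), Arhgap20 (−4.22 ± 0.42) and the sodium-calcium exchanger Slc8a1 (−4.17 ± 0.42) were lower.

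Phosphate handling and calcification genes had their highest levels in several classes. In astrocyte-like cells 8 of 15 were higher and 4 lower than the mean of the other classes (8 and 4 adjusted over the list alone), with 2 lower when doublets were kept and 1 with count splitting. The phosphate importer Slc20a1 was higher by 2.72 ± 0.18 and Jam2 by 2.69 ± 0.22, while Pdgfb was lower at −2.47 ± 0.58, a call lost with count splitting. Myorg (ENSMUSG00000046312, chromosome 4, 41495604 to 41503076, GRCm38) reached 99.5 ± 5.64 CPM in astrocyte-like cells and 3.67 ± 0.714 in the next class, oligodendrocyte precursor-like cells. The phosphate exporter Xpr1 (ENSMUSG00000026469, chromosome 1, 155275701 to 155417415) was also highest in astrocyte-like cells, at 314 ± 58.8 CPM against 224 ± 86.0 in committed oligodendrocyte precursor-like cells, and so was Slc20a1, at 121 ± 13.3 against 56.8 ± 8.14 in glutamatergic neuron-like cells. Slc20a2 (ENSMUSG00000037656, chromosome 8, 22476788 to 22569612), another phosphate importer, stood at 154 ± 23.9 CPM in astrocyte-like and 153 ± 9.73 in oligodendrocyte-like cells, a difference within the spread, and the highest class differed between the mice. Pdgfb (ENSMUSG00000000489, chromosome 15, 79995874 to 80014977), a growth factor that recruits pericytes, had 336 ± 15.9 CPM in endothelial-like and 262 ± 129 in microglia-like cells, the latter highest in mouse 2. Its receptor Pdgfrb (ENSMUSG00000024620, chromosome 18, 61045150 to 61085061) had 1074 ± 196 CPM in mural-like cells and 281 ± 12.2 in vascular leptomeningeal fibroblast-like cells. Jam2 (ENSMUSG00000053062, chromosome 16, 84774123 to 84825928), a junctional adhesion molecule, had 264 ± 37.8 CPM in endothelial-like and 163 ± 8.62 in astrocyte-like cells.

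Other members had their highest means in oligodendrocyte-like cells (Ank 303 ± 40.2 and Slc34a3 7.83 ± 2.87 CPM), endothelial-like cells (Abcc6 47.9 ± 6.94 and Cmpk2 53.5 ± 9.43 CPM), oligodendrocyte precursor-like cells (Nt5e 32.7 ± 2.12 CPM) and vascular leptomeningeal fibroblast-like cells (Enpp1 449 ± 197 CPM). Naa60 had 45.9 ± 0.812 CPM in GABAergic neuron-like and 43.6 ± 7.98 in border macrophage-like cells, a difference within the spread, and its highest class differed between the mice. Alpl had 317 ± 442 CPM in vascular leptomeningeal fibroblast-like cells, with 629 in mouse 1 and 4.49 in mouse 2, and 136 ± 5.29 CPM in endothelial-like cells. Slc17a1, Slc34a1 and Slc34a2 reached no more than 0.199, 0.101 and 0.0552 CPM in any class. No test compared the highest class with the next.

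**Figure D3:**
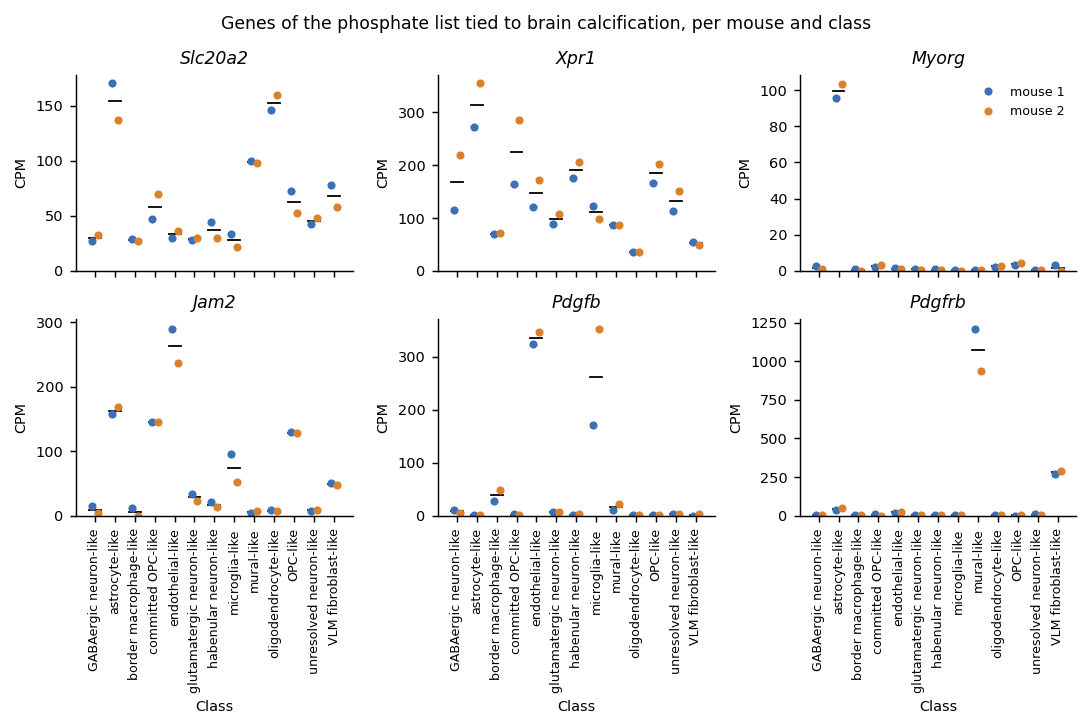
CPM (vertical axes) of 6 genes of the phosphate and calcification list in the 13 classes (horizontal axis), with points for mouse 1 (blue) and mouse 2 (orange) and a bar at their mean. Myorg reaches 99.5 ± 5.64 CPM in astrocyte-like cells and Pdgfrb 1074 ± 196 CPM in mural-like cells, while Slc20a2 is at 154 ± 23.9 CPM in astrocyte-like and 153 ± 9.73 CPM in oligodendrocyte-like cells.

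Microglia-like cells differed from the other classes in lysosomal, immune and risk genes. Tyrobp, an immune receptor adaptor, was higher by 8.99 ± 0.32 (1507 ± 232 against 153 ± 38.2 CPM), the protease Ctss by 8.92 ± 0.33 and the lipid-sensing receptor Trem2 by 8.43 ± 0.28 (1241 ± 226 against 26.8 ± 11.6 CPM). Among cytokines, Il1a and Tnf were higher by 9.55 ± 0.33 and 9.31 ± 0.31, at levels that were far apart in the mice: Il1a stood at 125 CPM in mouse 1 and 948 in mouse 2, and Tnf at 85.0 and 775. Atf3, a stress-induced transcription factor, was higher by 6.48 ± 0.29, with 156 CPM in mouse 1 and 2561 in mouse 2. Tyrobp (ENSMUSG00000030579, chromosome 7, 30413760 to 30417585) had an edgeR QL adjusted p of 2.11e-14, Trem2 2.69e-15 and Il1a 1.74e-14. Calls numbered 6442, 3765 higher and 2677 lower, with 6383 in the same direction in each mouse, and DESeq2 gave 3396 higher and 3814 lower. Cluster 11, led by Ccl4, Ccl3, Cd83 and Tnfaip3, held 84 of 895 microglia-like cells in mouse 1 and 506 of 521 in mouse 2. Cluster 7 held 743 and 4. Without cluster 11, an alternative chosen after seeing the data that leaves few cells of mouse 2, 3029 genes were higher and 2751 lower and the median of all genes moved by −0.12.

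Lysosome and phagocytosis genes had 29 higher and 1 lower of 32 (29 and 1 adjusted over the list alone, with none lower in mouse 2 alone or with doublets kept), including the complement receptor chain Itgam at 8.79 ± 0.32 and Laptm5 at 8.65 ± 0.30. Of the 32, 11 were highest in microglia-like cells in each mouse and 11, Tyrobp among them, in border macrophage-like cells. Alzheimer disease risk gene orthologs had 18 higher and 4 lower of 28 (18 and 4 adjusted over the list alone, with 2 lower when doublets were kept). The transcription factor Spi1 was higher by 8.53 ± 0.28, Inpp5d by 8.4 ± 0.30 and Ms4a6d by 8.22 ± 0.34. However, Ms4a6d was highest in border macrophage-like cells in each mouse, and was called lower in microglia-like cells when set against these. Cytokines, chemokines, complement and their receptors had 32 higher and 3 lower of 38 (32 and 3 adjusted over the list alone), with Il10ra at 9.23 ± 0.31 and Csf3r at 9.02 ± 0.36. Immediate early and stress genes had 24 higher and none lower of 32 (24 and 1 adjusted over the list alone), but 11 higher and 1 lower without cluster 11. Zfp36 stood at 5.85 ± 0.36, Socs3 at 5.46 ± 0.38, and Nfkbia at 5.52 ± 0.35 with 3.63 in mouse 1 and 6.43 in mouse 2. Outside the lists, the adenosine receptor Adora3 (9.72 ± 0.42), Sash3 (9.34 ± 0.40) and Naip2 (9.20 ± 0.38) were higher, the last uncertain because close paralogs can share its reads. Pknox2 (−4.75 ± 0.49), the synapsin Syn3 (−4.62 ± 1.01) and the Hippo pathway factor Tead1 (−4.58 ± 0.43) were lower, though Syn3 lost its call at a mitochondrial limit of 5% and Tead1 with the looser cell filter.

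Microglia-like and border macrophage-like cells, 2 kinds of brain macrophage, differed in antigen presentation genes. The class II genes H2-Aa and H2-Eb1 were lower in microglia-like cells at −9.70 ± 0.77 (1.89 ± 1.55 against 1501 ± 739 CPM) and −9.42 ± 0.69 (2.19 ± 0.0112 against 1725 ± 1214 CPM). Apoe was lower at −6.44 ± 0.64 (278 ± 142 against 26469 ± 2956 CPM), as was the chemokine Ccl7 at −7.77 ± 0.71. Cd9, a tetraspanin, was higher in microglia-like cells by 3.65 ± 0.36 (951 ± 122 against 92.0 ± 33.9 CPM), Itgb5 by 3.03 ± 0.36 and Abi3 by 4.13 ± 0.58. H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823) had an edgeR QL adjusted p of 1.67e-07, Apoe 8.57e-07 and Cd9 8.36e-07. Calls numbered 2216, 1236 higher and 980 lower, with 2166 in the same direction in each mouse. Without microglia-like cluster 11 the split was 852 and 1101, and DESeq2 size factors, which moved the median of all genes by −0.12, gave 1002 and 1096. The looser cell filter gave 1275 and 1382. Transcripts typical of other cell types were present in border macrophage-like cells: in mouse 2 (50 cells) the mean was 148 haemoglobin UMIs per cell with a median of 0, and the myelin gene Mal stood at 365 CPM in mouse 1 and 42.4 in mouse 2.

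Antigen presentation genes had none higher and 7 lower of 16 in microglia-like cells (0 and 7 adjusted over the list alone), with H2-Ab1 at −7.91 ± 0.58 and Ciita, the class II transactivator, at −6.92 ± 0.90. Lysosome and phagocytosis genes had 10 higher and 4 lower of 32 (10 and 5 adjusted over the list alone, and 6 higher without cluster 11). The receptor Axl was lower at −3.14 ± 0.37, and Itgam at 2.64 ± 0.63 lost its call without the mouse block. Cytokines, chemokines, complement and their receptors had 9 higher and 8 lower of 38 (12 and 8 adjusted over the list alone), with 4 lower by DESeq2 and 5 without the gene filter. Complement C4b was lower at −6.47 ± 0.57, as was Ccl24 at −6.58 ± 0.43, a call lost by DESeq2. Alzheimer disease risk gene orthologs had 7 higher and 4 lower of 28 (9 and 4 adjusted over the list alone, with 2 lower in mouse 2 alone or with doublets kept). The kinase Ptk2b was higher by 2.43 ± 0.38, and Trem2 at 2.62 ± 0.57 lost its call without the mouse block. Outside the lists, Csmd3 was higher by 5.86 ± 0.48.

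Oligodendrocyte-like cells differed from oligodendrocyte precursor-like cells in sterol synthesis, glutamate receptors and channels. Hmgcs1, an early enzyme of cholesterol synthesis, was higher by 2.25 ± 0.36 (259 ± 52.9 CPM), and Ebp, a sterol isomerase, by 2.59 ± 0.27 (65.5 ± 8.74 against 14.6 ± 2.42 CPM). Grin3a and Gria3, subunits of NMDA and AMPA receptors, were lower at −6.80 ± 0.47 (4.22 ± 1.54 against 620.2 ± 95.6 CPM) and −6.58 ± 0.50 (5.07 ± 3.36 against 586 ± 2.91 CPM). Ccnd1, a cyclin of the G1 phase, was lower at −7.41 ± 0.69 (2.14 ± 0.771 against 490.4 ± 149 CPM), as was the Kv4 channel Kcnd2 at −6.31 ± 0.56 (39.8 ± 18.1 against 4021 ± 158 CPM). Hmgcs1 (ENSMUSG00000093930, chromosome 13, 119690379 to 119708260) had an edgeR QL adjusted p of 3.43e-05, Grin3a 1.4e-09 and Ccnd1 4.46e-08. Calls numbered 6448, 2639 higher and 3809 lower, with 6332 in the same direction in each mouse. DESeq2 size factors moved the median of all genes by −0.22 and gave 2040 higher and 4162 lower, whereas no gene filter moved it by 0.20 and gave 3327 and 3727.

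Cholesterol synthesis genes had 15 higher and none lower of 24 (15 and 0 adjusted over the list alone), with Idi1 at 2.17 ± 0.38 and Sc5d at 2.15 ± 0.24. Ionotropic glutamate receptors had none higher and 14 lower of 18 (0 and 14 adjusted over the list alone), including Grid1 at −6.62 ± 0.56 and Grik3 at −5.26 ± 0.43. Potassium channels had 3 higher, Kcna1, Kcna6 and Kcnj10, and 24 lower of 32 (3 and 24 adjusted over the list alone). Kcnd3 (−6.65 ± 0.59), the leak channel Kcnk3 (−6.33 ± 0.58) and Kcnj6 (−6.08 ± 0.68) were among the lower. Cell cycle genes had 2 higher and 14 lower of 22 (2 and 15 adjusted over the list alone). Ccnd2 was lower at −6.21 ± 0.75, the cell cycle inhibitor Cdkn2d was higher by 1.97 ± 0.29, and Pcna, a replication clamp, by 1.53 ± 0.33, with 2.54 in mouse 1 and 1.24 in mouse 2. Outside the lists, Nipal4 (8.55 ± 0.89), Olfml1 (7.16 ± 0.81) and Dock5 (7.13 ± 0.71) were higher, and the transcription factor Meox1 (−9.19 ± 0.75) was lower. Transcripts of mature oligodendrocytes were present in the precursor class of mouse 1, with Ptgds at 839 CPM against 62.8 in mouse 2 and Mobp at 79.6 against 22.2. Precursor-like cluster 37, led by Top2a, Cenpf and Mki67, held only 3 cells in mouse 1 and 18 in mouse 2, and how much of the cell cycle difference these carry was not tested. Ribosomal protein messenger RNA made up 0.389% and 0.347% of UMIs in precursor-like cluster 31 (61 and 23 cells), against 2.0% and 2.03% in cluster 5 (78 and 920 cells). Oligodendrocyte-like cluster 1 held 32 cells of mouse 1 and 1389 of mouse 2, and cluster 2 held 1120 and 248.

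Endothelial-like cells differed from mural-like cells, the pericyte-like and smooth muscle-like cells together, in barrier transport, signalling and matrix. The amino acid transporters Slc38a5 and Slc7a5 were higher by 7.06 ± 0.83 (127 ± 1.35 against 1.05 ± 0.598 CPM) and 6.49 ± 0.60 (299 ± 65.3 against 4.02 ± 3.61 CPM), and the efflux pump Abcc4 by 6.64 ± 0.43. Edn1, the vasoconstrictor endothelin, was higher by 6.49 ± 0.71 (183 ± 22.7 against 2.17 ± 2.24 CPM), while its receptor Ednra was lower at −6.70 ± 0.34 (3.02 ± 0.462 against 324 ± 11.9 CPM). Pdgfrb, the pericyte growth factor receptor, was lower at −5.70 ± 0.57, and Jam2 was higher by 5.76 ± 0.49. Abcc4 (ENSMUSG00000032849, chromosome 14, 118482692 to 118706219) had an edgeR QL adjusted p of 2.55e-09, Ednra 9.59e-10 and Pdgfrb 2.89e-07. Calls numbered 3772, 1778 higher and 1994 lower, with 3767 in the same direction in each mouse. At a mitochondrial limit of 5%, where no smooth muscle-like class formed, 1984 were higher and 1566 lower.

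Blood-brain barrier transport and junction genes had 23 higher and none lower of 24 (24 and 0 adjusted over the list alone), among them the tricellular junction gene Lsr at 6.46 ± 0.66. Vascular signalling genes had 23 higher and 9 lower of 44 (24 and 10 adjusted over the list alone), with the receptor Flt4 at 6.38 ± 0.77. Basement membrane genes had 4 higher and 8 lower of 22 (4 and 8 adjusted over the list alone). The collagen Col4a5 (−5.97 ± 0.46) and the laminin Lama2 (−5.57 ± 0.65) were lower, and the integrin Itga6 (5.89 ± 0.60) and fibronectin, Fn1, (5.05 ± 0.54) were higher. Phosphate handling and calcification genes had 6 higher and 2 lower of 15 (6 and 2 adjusted over the list alone, with 1 lower at a mitochondrial limit of 5%), including Alpl at 5.78 ± 1.02 and the mitochondrial kinase Cmpk2 at 5.06 ± 0.56. Outside the lists, the transcription factor Sox7 (6.72 ± 0.82), Nxpe2 (6.69 ± 0.74) and the receptor Ly75 (6.56 ± 0.76) were higher, and C1qtnf2 (−6.55 ± 0.77) and the potassium channel subunit Kcne4 (−6.42 ± 0.90) were lower. In endothelial-like cells of mouse 1 the mean was 416 haemoglobin UMIs per cell, with a median of 4.

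**Figure D4:**
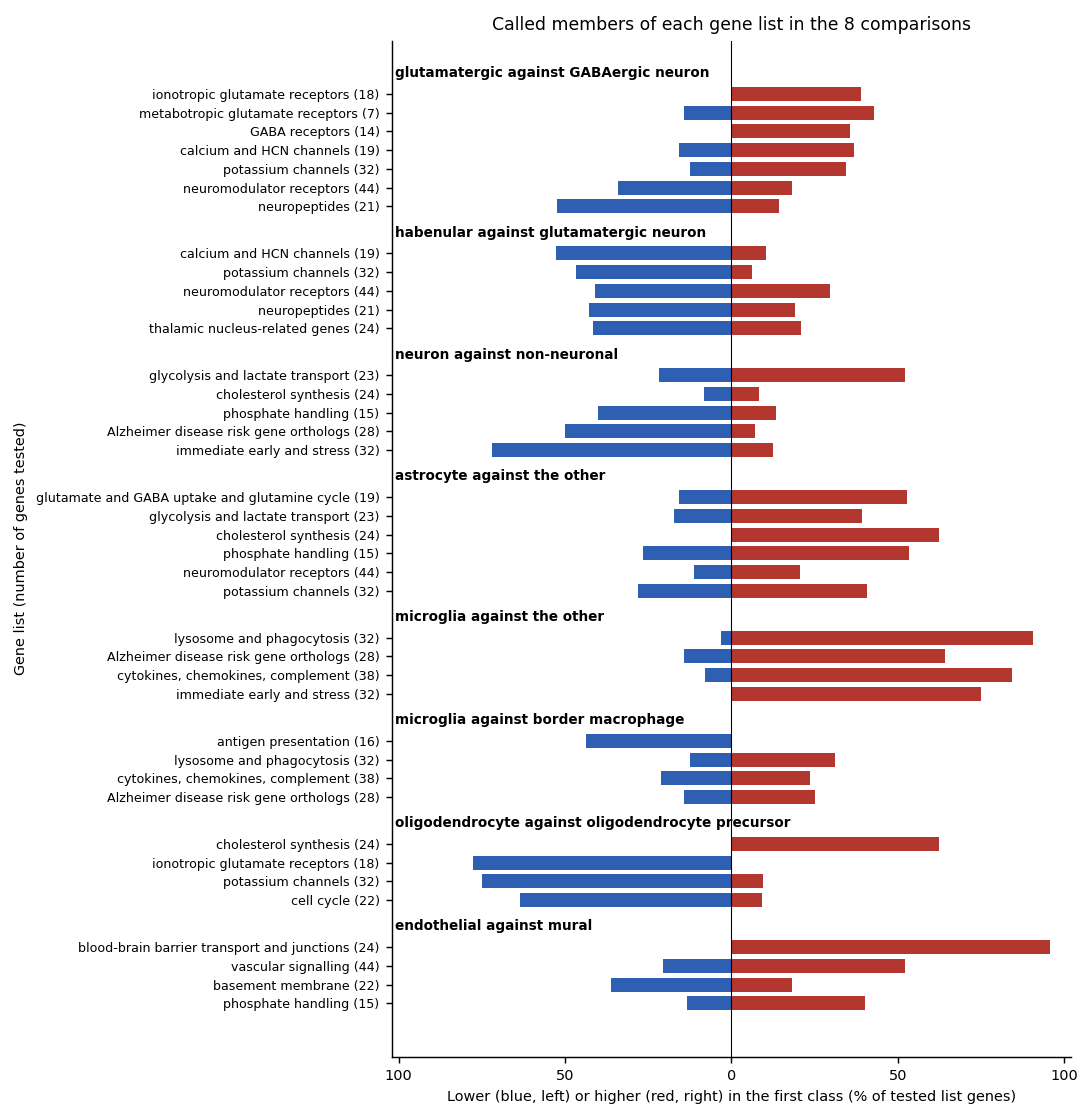
Members of each gene list called higher (red, right) or lower (blue, left) in the first class of each of the 8 comparisons, as a percentage of the list genes tested (horizontal axis), with the number tested beside each list name (vertical axis). In endothelial-like against mural-like cells 23 of 24 barrier genes were higher, and in oligodendrocyte-like against precursor-like cells 14 of 18 ionotropic glutamate receptors were lower.

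Across genes at 50 CPM or more, which are not independent replicates, the Pearson correlation of log2 CPM was 0.964 for oligodendrocyte-like, 0.951 for astrocyte-like, 0.829 for microglia-like, 0.779 for border macrophage-like and 0.673 for vascular leptomeningeal fibroblast-like cells. The sums of these classes differ in depth, with 56541296 UMIs in mouse 1 and 51455678 in mouse 2 for oligodendrocyte-like, 11367708 and 5038068 for microglia-like, 1910057 and 448259 for border macrophage-like and 293918 and 445796 for fibroblast-like cells, so the correlations are not comparable between classes. In microglia-like cells 85 genes were at least 4-fold higher in mouse 2 and 4 in mouse 1. Immediate early and stress genes had a median log2 ratio of mouse 2 over mouse 1 of 2.63 in microglia-like cells, where 95% of 10000 random lists matched on expression lay between −0.31 and 0.17. The same list stood above the random range in all 13 classes, from 0.63 in GABAergic neuron-like to 4.62 in vascular leptomeningeal fibroblast-like cells. Cytokines, chemokines, complement and their receptors had a median of 0.34 in microglia-like cells, above a random range of −0.37 to 0.08, but lay below the random range in glutamatergic (−0.72) and unresolved neuron-like (−0.44), committed oligodendrocyte precursor-like (−0.46) and endothelial-like cells (−0.20). These values compare 2 libraries and have no replicate check.

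**Figure D5:**
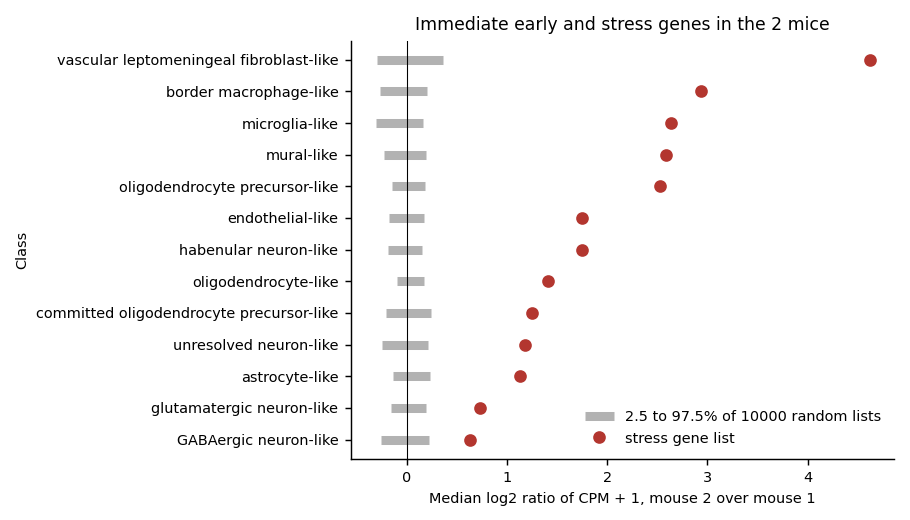
Median log2 ratio of CPM + 1 of mouse 2 over mouse 1 for the immediate early and stress genes (red points, horizontal axis) in the 13 classes (vertical axis), with the central 95% of 10000 random lists matched on expression (grey bars). All points lie to the right of the bars, from 0.63 in GABAergic neuron-like cells to 4.62 in vascular leptomeningeal fibroblast-like cells.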

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

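No named gene changed direction under any alternative. With 1 mouse left out this was fixed in advance, since genes were named only if each mouse had the same direction. The larger side of the split of called genes turned in 3 comparisons, microglia-like against the others, microglia-like against border macrophage-like and endothelial-like against mural-like, and the cause was not tested. All 120 counts of called genes (8 comparisons under 15 alternatives) stayed within 1.5 times the reported count, the largest ratio being 1.36. Glutamatergic against GABAergic calls ran from 1572 with no replicate block to 2670 with list genes in clustering, and neuron-like against non-neuronal calls from 5963 with count splitting to 7535 by DESeq2. With no replicate block, that is without pairing classes by mouse, calls numbered 3007 for habenular, 5432 for astrocyte-like, 6186 for microglia-like and 1876 for microglia-like against border macrophage-like cells. With 1 mouse left out, called genes that kept direction and size numbered 1827 to 2050 for glutamatergic against GABAergic, 3360 to 3453 for habenular and 5836 to 5840 for microglia-like cells. Of the list counts, 1111 stayed and 59 moved. For phosphate genes in their highest class 116 values stayed and 8 moved, 3 of them at the mitochondrial limit of 5%, and the highest class itself differed under some alternative for Naa60, Slc20a2, Slc34a1 and Slc34a2. With mouse 1 left out 66 of the 200 named log2 values moved by at least the SD between the mice, and with mouse 2 left out 73. With a single value per mouse, neither value can lie as far as that SD from their plain mean. These counts therefore reflect where the estimate of the fit lies between the mice, and do not measure dependence on a mouse. Under the other alternatives 42 values of named genes lost the call. Mean shares moved as follows, and the cause was not tested. At a mitochondrial limit of 5% they were 1.04% for GABAergic, 1.98% for habenular, 20.8% for oligodendrocyte-like, 0.583% for fibroblast-like and 8.86% for unnamed cells, and no smooth muscle-like class formed. With the looser cell filter they were 0.634% for GABAergic, 28.9% for oligodendrocyte-like and 15.1% for unnamed cells, and at resolution 2 0.886% for GABAergic cells. Simulated 2-fold changes were recovered at 13% between microglia-like and border macrophage-like cells and at 98% between neuron-like and non-neuronal classes, so a missing call between the macrophage classes does not show equal levels. The alternatives without low-UMI neuron clusters and without microglia-like cluster 11 were chosen after seeing the data.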

Other observations

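The class of highest CPM was also read out for list genes. In each mouse, 9 of 24 cholesterol synthesis genes were highest in committed oligodendrocyte precursor-like cells, an intermediate stage of myelin-forming cells. Among them was Sqle, squalene epoxidase (79.3 ± 12.4 CPM, with 52.6 ± 16.7 in astrocyte-like cells). Of 22 basement membrane genes, 11 were highest in vascular leptomeningeal fibroblast-like cells, with the laminin Lama1 at 1293 ± 125 CPM. Of 18 ionotropic glutamate receptors, 7 were highest in oligodendrocyte precursor-like cells, and Gria1, an AMPA receptor subunit, was highest in astrocyte-like cells (1888 ± 311 CPM, with 1245 ± 58.1 in habenular neuron-like cells).

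Of 44 vascular signalling genes, 21 were highest in endothelial-like and 5 in astrocyte-like cells. Among the latter, Wnt7a, a Wnt ligand of barrier formation, stood at 91.2 ± 5.57 CPM and 23.6 ± 1.10 in oligodendrocyte precursor-like cells, and the growth factor Vegfa at 213 ± 27.3 and 86.3 ± 25.1 CPM. The nuclear receptor Rorb, used as a thalamic neuron gene, reached 942 ± 143 CPM in astrocyte-like and 439 ± 49.9 CPM in glutamatergic neuron-like cells. These genes were picked after their values were seen, and no test was run on them. CPM are relative to the RNA of a class, so levels per cell can rank differently. Median UMIs per cell were 13106 in astrocyte-like, 46898.5 in glutamatergic neuron-like and 32234 in habenular neuron-like cells.

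The 3 patterns weighed here were noticed in the data. The tests of tissue handling, of free RNA from stressed cells, of nuclei without cytoplasm and of free RNA from lysed red cells were chosen only after the result was seen. The mice form 1 group, so no biological explanation was tested.

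Immediate early and stress genes were higher in mouse 2 in microglia-like cells, with a median log2 ratio of 2.63. Handling of the tissue could do this to every cell, and the list median lay above the random range in 12 of the 12 other classes. Free RNA is unlikely as the main source, since the class with least held a median of 1.64% of the microglia-like level per cell. A different mix of clusters may carry much of the difference. However, the clusters were formed from these same cells with no integration, and cluster 7 held 743 cells of mouse 1 and 4 of mouse 2. The mix is therefore not an explanation separate from a difference between the mice. Within cluster 11 (84 cells of mouse 1 and 506 of mouse 2) the median was still 0.42 with a random range of −0.13 to 0.12. This remainder is not due to the mix of clusters, but a single cluster cannot show whether cell states inside it were mixed differently. Handling and a difference between the animals cannot be told apart with 1 library each.

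In each mouse, glutamatergic cluster 13 had fewer UMIs and more Malat1 and Meg3 than clusters 10 and 15, and so did habenular cluster 22 against cluster 18. Bare nuclei are unlikely, since the share of mitochondrial RNA was at least 1.21 times that of the reference clusters. Loss of cytosolic RNA could explain the pattern, as ribosomal protein messenger RNA was at most 0.103 times the reference. Unspliced RNA of long genes may be part of it, since the log2 ratio rose with gene span at a Spearman correlation of at least 0.686 across genes. The correlation included the ribosomal protein genes and cannot separate unspliced RNA from a loss of RNA of short genes. Whether intron reads were counted is not given in the sources used here. A lower ribosomal protein share was also seen in oligodendrocyte precursor-like cluster 31 and astrocyte-like cluster 14, where these tests were not run.

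In mouse 1 haemoglobin UMIs averaged 416 per endothelial-like cell with a median of 4, and 444 per GABAergic neuron-like cell with a median of 7.5. Free RNA of lysed red cells is unlikely, since the class with least held 0.755% of the endothelial-like mean per cell. Red cells captured with single cells could explain it, as the 10% of cells with most haemoglobin held 99.1% of it in endothelial-like and 98.4% in GABAergic neuron-like cells.

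In mouse 1, 3 of 1033 astrocyte-like cells held 39045 of 39116 Ttr UMIs of that class. They averaged 57.7 UMIs of Folr1, 0 of Aqp4 and 1.67 of Slc1a3, against 0, 9.28 and 17.9 in the other astrocyte-like cells of mouse 1. Ttr and Folr1 were listed as markers of choroid plexus epithelial cells and Aqp4 and Slc1a3 of astrocytes, so these 3 cells are likely misplaced. They stayed in the tested sum. Of 3550 genes compared in all 13 classes, Fos (median log2 ratio 4.55), Jun (3.20) and AY036118 (2.45) were higher in mouse 2 in every class, and Cdk8 (−1.71) and Gm42418 (−1.29) lower. Only genes beyond a fixed cut-off in every class are given, with Gm42418 at −0.819 in its weakest class. Genes with smaller differences of the same direction in every class are not covered. In endothelial-like cells the median log2 ratio of mouse 2 over mouse 1 was 2.01 for GABA receptors, 1.88 for ionotropic glutamate receptors, 1.73 for potassium channels and 1.36 for calcium and HCN channels, above the random range for each. In the same class the neuronal transcripts Meg3 (103 CPM in mouse 1 and 343 in mouse 2) and Kcnip4 (74.7 CPM in mouse 1 and 607 in mouse 2) were higher in mouse 2, whose share of neuron-like cells was 27.3% against 8.49%. The potassium channel median was also above the random range in microglia-like (1.11), mural-like (0.98), border macrophage-like (0.79), fibroblast-like (0.59), oligodendrocyte-like (0.55), committed precursor-like (0.55) and GABAergic neuron-like cells (0.27), and below it in glutamatergic neuron-like cells (−0.31). The cholesterol synthesis list had a median log2 ratio above the random range in glutamatergic (0.82), habenular neuron-like (0.80), astrocyte-like (0.62), mural-like (0.57) and border macrophage-like cells (0.37), and inside it in the other classes, from −0.55 in fibroblast-like to 0.17 in GABAergic neuron-like cells. Glutamatergic cells were spread differently over clusters, with cluster 10 holding 23 of 204 in mouse 1 and 610 of 1600 in mouse 2. Cluster 15 held 113 and 259, and how far this shift carries the glutamatergic medians was not tested. Unnamed clusters included 1 led by B cell markers (15 and 17 cells in mouse 1 and mouse 2), 1 by T or NK cell markers (14 and 11) and 1 by neutrophil markers (15 and 4).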
